A study of Ericerus pela with 4 samples.

How the data were processed

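Whole bodies of the white wax scale insect, Ericerus pela, were homogenized in buffer and sieved, per the labels' protocols, and single cells of the suspension were captured in microwells with barcoded beads (BD Rhapsody). A bead carries many oligonucleotides that share a cell barcode and differ in their unique molecular identifiers, so that copies of 1 captured mRNA molecule can be counted once after sequencing of its 3' end. There were 4 libraries, 1 each of male pupae, male adults, female nymphs and female adults. How many animals went into a library is not given in the sources used here.

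The deposited values were counts, one whole number of molecules for each cell barcode and gene ID. Per the file headers, the authors made these counts with the BD WTA Rhapsody Analysis Pipeline 1.9.1, and the counts are those left after its correction of errors in the molecular identifiers. The submitters' processing notes name Seurat 4.0.6, but the deposited counts carried no normalization. The genome build, the aligner and the rule by which barcodes were kept as cells are not given in the sources used here. Per the file headers, the pipeline was run on the male adult library 22 days before the last run and on the female adult library 1 day before it. The male adult and female adult libraries were therefore each alone in their date, and date and group cannot be told apart in any comparison that holds one of them. Male pupa and female nymph shared a date. These are dates of the pipeline run and not of capture or sequencing. With 1 library per group, other differences in how libraries were handled cannot be told apart from group in any comparison. Reads that near-identical gene copies share may have been split between IDs, and this could not be checked without sequences.

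The files give gene IDs and do not pair them with names, and no annotation was used here. The lists of cell type markers and gene groups that had been fixed for this tissue could therefore not be matched, no cluster was given a cell type name, and no function is stated for any ID. The groups, the comparisons, the thresholds and the rule for named genes were chosen before the data were examined. By that rule, the IDs with the largest and smallest ratio in a comparison were taken among IDs with at least 100 molecules over both libraries, with molecules in at least 20 barcodes of the higher library and at most 20% of its molecules from 1 barcode. The rule ranked 10 IDs each way, and of IDs without a name it printed at most 2 higher and 2 lower per comparison. Members of the gene lists, the 10 most abundant IDs of a library and the 10 leading IDs of a cluster were also covered by it and are not printed, for want of names.

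Molecules were summed per ID over all 23864 deposited barcodes of the 4 libraries and expressed per 1000000 molecules of the library. The comparisons were male adult against male pupa, female adult against female nymph, female adult against male adult, and female nymph against male pupa. With 1 library per group there is no replicate check, so no test was made and no p-value is given. Ratios carry exact conditional binomial 95% intervals and shares of barcodes carry exact Clopper-Pearson 95% intervals, both of which cover counting error only. A count below 3 molecules in a library was set to 3 for ratios on the log2 scale, and a fold against 0 molecules is written as at least the fold against that floor. Where the lower library held 1 to 3 molecules, the interval is given. Numbers of IDs past 4-fold describe the size of the difference between library sums and are not numbers of tested changes. IDs with at least 100 molecules over the 4 libraries, 8378 of 10860, entered correlations and 6 4-way patterns, in which an ID had to be at least 4-fold higher in each of one pair of libraries than in each of the other pair.

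For clusters, barcodes with at least 200 IDs were scaled to 10000 molecules and log-transformed. The 2000 most variable IDs, ranked within libraries in 20 bins of the mean, gave 30 principal components. A graph of 15 nearest neighbours was divided with the Leiden method at resolution 0.8, without integration of libraries. Each library was given equal weight when the makeup of a cluster was described. A cluster was called one-sex when at least 95% of its weight came from libraries of that sex, and shared when each of the 4 libraries had at least 5%. Doublets were kept. Scrublet marked 61 of 21891 barcodes, or 0.279%, which is too few for the caller to have worked, so an additional run left out the 5% of barcodes with the highest scores in each library. To compare libraries of different depth, barcodes with at least 500 molecules were thinned to 500 without replacement and shallower barcodes were left out.

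Alternatives for the sums were median-of-ratios scaling over 6472 IDs with at least 50 molecules in every library, a total without the 20 most abundant IDs of any library, barcodes with at least 200 IDs or 500 molecules, the mean over barcodes, and sums without the 1% of barcodes with the most molecules. Median-of-ratios scaling moved all log2 ratios by 0.05 for male adult against male pupa, 0.18 for female adult against female nymph, 0.50 for female adult against male adult and 0.38 for female nymph against male pupa. Correlations were repeated with a minimum of 20 molecules and without the 100 most abundant IDs. Clusters were repeated at resolutions 0.4 and 1.2, with at least 100 or 500 IDs per barcode, with IDs centred and scaled within libraries and without called doublets. Equal-depth values were repeated at 1000 molecules and without thinning. Further alternatives were added after seeing the data, namely patterns without the male adult library or with a minimum of 20 molecules, the correlation without the IDs of the patterns, and clusters without the highest doublet scores, with thinned barcodes, or without the 3826 IDs that differed 4-fold in a comparison.

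The calculations were tested on simulated data. For the 4 comparisons, 100 of 100 IDs simulated with an 8-fold difference and 0 of 100 with a 2-fold difference passed 4-fold. In the simulation of male adult against male pupa, with 7764 IDs, 0 of 7564 unchanged IDs passed 4-fold, and over the 6876 IDs with intervals 95.3% of intervals held the simulated fold. All 200 IDs simulated in a 4-way pattern were found among 8400. For the clusters, 5 simulated groups of barcodes at the depths of the 4 libraries were never mixed within a cluster (homogeneity 1.0), but came out as 10 clusters with an adjusted Rand index of 0.653. The splits followed depth, with cluster medians from 642 to 11055 molecules, and 0 of the 10 clusters were one-sex. At resolution 0.2 the 5 groups came out as 5 clusters. Thinned barcodes of 1 simulated profile had medians of 395 IDs at the depths of 3 libraries and 394 at that of the male adult library. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scanpy 1.11.5 and matplotlib 3.10.9.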

Results

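Single-cell transcriptomes were collected from whole bodies of Ericerus pela, a scale insect reared for the wax that its male nymphs secrete. The sexes develop differently. Females pass through nymphal stages to a wingless adult that keeps a nymph-like body, whereas males pass through a pupal stage and become winged adults. The 4 libraries covered male pupae, male adults, female nymphs and female adults, with 1 library per group and therefore no measure of the spread between animals. The values are counts of molecules per gene ID, and the files do not pair these IDs with gene names.

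The male pupa library held 4437 barcodes and 23326858 molecules, and the male adult library 8854 barcodes and 11973499 molecules. The female nymph library held 5949 barcodes and 34560763 molecules, and the female adult library 4624 barcodes and 38598651 molecules. The male adult library was the shallowest per barcode, with a median of 599 molecules (quartiles 352 and 1278) against 3238 in male pupa, 2860 in female nymph and 6688.5 in female adult. Median numbers of IDs per barcode were 1407 in male pupa, 351 in male adult, 1046 in female nymph and 1840 in female adult. The most abundant ID took 2.35% of molecules in male pupa and 6.87% in male adult, and another took 4.33% in female nymph and 4.23% in female adult. A floor of 3 molecules was worth 0.129 molecules per 1000000 in male pupa, 0.251 in male adult, 0.0868 in female nymph and 0.0777 in female adult.

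**Figure D1:**
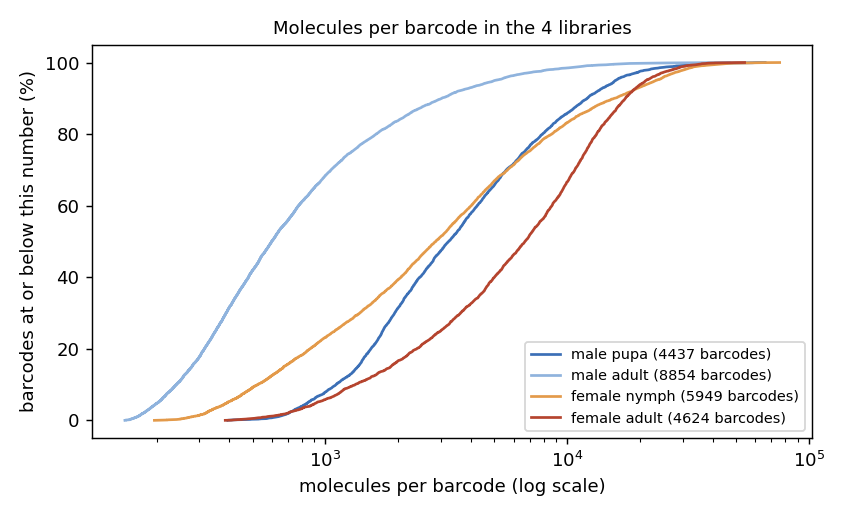
Cumulative percentage of barcodes (vertical axis) against molecules per barcode on a log scale (horizontal axis), 1 line per library. The male adult line lies to the left of the others, with a median of 599 molecules against 2860 to 6688.5 in the other libraries.

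Once barcodes were thinned to 500 molecules, the libraries came close to each other. The median barcode then held 363 IDs in male pupa, 338 in male adult, 328 in female nymph and 310 in female adult. This left out 14 barcodes of male pupa, 3712 of male adult, 546 of female nymph and 24 of female adult. The female adult library, with the most IDs per barcode before thinning, had the fewest at equal depth, and the male adult library moved from fewest to above both female libraries.

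Across 8378 IDs, the female libraries were the most alike pair, with a Spearman correlation across IDs of 0.934. The male libraries had a correlation of 0.814. Male pupa was closer to female adult (0.798) than to female nymph (0.749), and male adult was least like female adult (0.678). IDs are not independent replicates, and these correlations describe 4 libraries.

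The comparison of male adult with male pupa asks what differed between the last immature stage and the adult in males. Among 7788 IDs, 352 were at least 4-fold higher in male adult, where they took 13.3% of molecules against 1.60% in male pupa. Another 734 were at least 4-fold lower in male adult and took 2.001% of its molecules against 17.7% in male pupa. The median ID differed 1.64-fold in either direction. The most strongly higher IDs were Ech006248, with 6916 molecules in male adult and 90 in male pupa (150-fold, 95% interval 122 to 186), and Ech003336, with 9600 and 128 molecules (146-fold, 123 to 175). The most strongly lower were Ech008062, with 22 molecules in male adult against 172244 in male pupa (4019-fold, 2654 to 6413), and Ech010557, with 7 against 41481 (3042-fold, 1476 to 7566). The 22 molecules of Ech008062 in male adult came from 7 barcodes, and 68.2% of them lay in 1 barcode. Its interval treats molecules as independent and is therefore too narrow. The male adult and female adult libraries were each alone in their processing date, so date and group cannot be told apart in this comparison, nor in the comparisons of female adult with female nymph and with male adult.

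The comparison of female adult with female nymph showed the smallest differences of the 4. The median ID differed 1.28-fold, and of 7453 IDs 276 were at least 4-fold higher and 134 at least 4-fold lower in female adult. The higher IDs took 4.62% of female adult molecules and 0.302% of female nymph molecules. The lower IDs took 0.0990% of female adult molecules and 0.594% of female nymph molecules. The IDs with the most extreme higher ratios were the pair that was lowest in male adult against male pupa. Ech010557 had 26935 molecules in female adult and 0 in female nymph, or at least 8039-fold more, and Ech008062 had 21538 against 3 (6428-fold, 2199 to 31174). On the lower side, Ech010854 had 3 molecules in female adult against 509 (189-fold, 64.5 to 922), and Ech007459 had 0 against 373, or at least 139-fold fewer.

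The comparison of female adult with male adult, a difference of sex at the adult stage, was the widest. The median ID differed 2.06-fold, and of 7674 IDs 709 were at least 4-fold higher and 1264 at least 4-fold lower in female adult. The higher IDs took 38.4% of female adult molecules against 2.45% in male adult, and the lower IDs took 26.2% of male adult molecules against 2.49% in female adult. This split depended on the scaling. With median-of-ratios scaling, which raised all log2 ratios by 0.50, the numbers were 931 higher and 957 lower. Ech010436 had 284437 molecules in female adult and 5 in male adult (17647-fold, 7562 to 54349), and Ech003845 had 70583 against 0, or at least 7298-fold more. Ech006855 had 0 molecules in female adult against 42287 in male adult, or at least 45440-fold fewer, and Ech004386 had 0 against 27240, or at least 29271-fold fewer.

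Sex differences were also wide at the immature stages, although a nymph and a pupa are different stages. Of 7984 IDs, 447 were at least 4-fold higher and 1289 at least 4-fold lower in female nymph than in male pupa, and the median ID differed 1.64-fold. The higher IDs took 31.8% of female nymph molecules against 1.54% in male pupa, and the lower IDs 19.8% of male pupa molecules against 1.02%. Ech010489 had 76149 molecules in female nymph and 0 in male pupa, or at least 17132-fold more, and Ech003845 had 83644 against 4 (14114-fold, 5512 to 51802). Ech008062 had 3 molecules in female nymph against 172244 in male pupa (85065-fold lower, 29107 to 412491), and Ech010557 had 0 against 41481, or at least 20486-fold fewer.

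IDs that separated the sexes at both stages were far more numerous than IDs that separated immature from adult libraries in both sexes. In the 4-way comparison of 8378 IDs, 758 were at least 4-fold higher in both male libraries than in both female libraries. They took 7.83% of molecules in male pupa and 10.8% in male adult, against 0.261% in female nymph and 0.283% in female adult. The 237 IDs higher in both female libraries took 23.6% in female nymph and 22.0% in female adult, against 0.742% in male pupa and 0.459% in male adult. By contrast, 16 IDs were higher in both immature libraries and 1 in both adult libraries. The crossed pairing held 154 IDs higher in both male pupa and female adult, and 7 higher in both male adult and female nymph. The 154 IDs took 5.32% of molecules in male pupa and 3.01% in female adult, against 0.0965% in male adult and 0.120% in female nymph. Without the male adult library, the remaining 3 libraries gave 1101 IDs higher in male pupa alone and 317 in both female libraries. They gave 120 IDs higher in the immature libraries, 44 in the adult library, 283 in male pupa and female adult, and 77 in female nymph alone. Leaving out a library removes a condition from each pattern, which can raise its number of IDs.

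**Figure D2:**
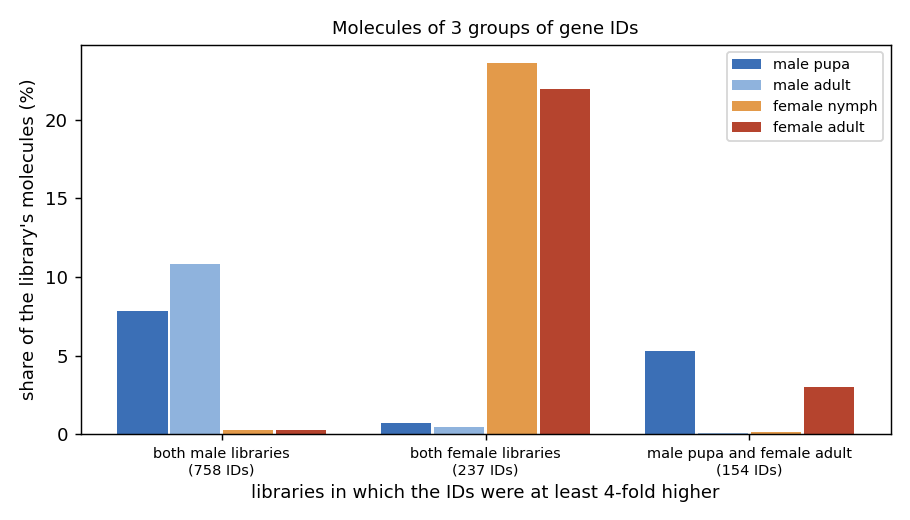
Share of each library's molecules in percent (vertical axis) taken by 3 groups of gene IDs, with 1 bar per library. The 237 female-higher IDs took 23.6% and 22.0% of the female libraries, and the 154 IDs of the third group took 5.32% of male pupa and 3.01% of female adult.

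The comparison of stage ratios between the sexes asks whether the same IDs differed with stage in males and females. Across 8378 IDs, the log2 ratio of adult to pupa in males and the log2 ratio of adult to nymph in females had a Pearson r of -0.388 and a Spearman rho of -0.334. The counting interval of r, from 200 resamples of the counts, was -0.389 to -0.378. The ratios come from separate pairs of libraries and share none. Sex ratios, female over male, had an r of 0.497 and a rho of 0.397 between the adult and the immature pair. At 4-fold, 207 IDs were lower in male adult than in male pupa and higher in female adult than in female nymph, where independent lists of 802 and 328 IDs would share 31.4. The reverse combination held 35 IDs, while 6 were higher and 33 lower in the adults of both sexes. Without the IDs of the 6 4-way patterns, r was -0.24. With molecules summed over the 4 clusters that held all 4 libraries, r across 5286 IDs was -0.112. The stage labels have no independent check in the files.

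**Figure D3:**
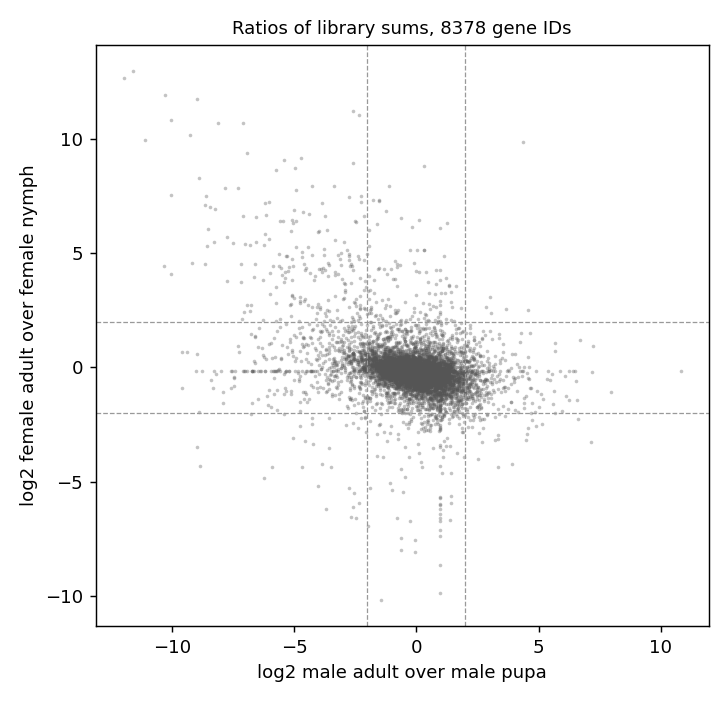
Log2 ratio of female adult over female nymph (vertical axis) against log2 ratio of male adult over male pupa (horizontal axis), 1 point per gene ID, for 8378 IDs, with counts below 3 molecules set to 3. Dashed lines mark 4-fold. The upper left field holds 207 IDs and the upper right field 6.

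Clustering of 21891 barcodes with at least 200 IDs gave 46 clusters, most of them filled by 1 sex. Of these, 22 had at least 95% of their weight from male libraries and 17 from female libraries, and 4 held all 4 libraries. One-sex clusters held 87.4% of barcodes with libraries weighted equally, and shared clusters 4.56%. When the 3826 IDs that differed 4-fold between libraries were kept out of the variable IDs, one-sex clusters still held 81.4% and shared clusters 7.78%. The female libraries lay together more often than the male ones. Clusters with at least 95% of their weight from a single library numbered 10 for male pupa, 6 for male adult, 1 for female nymph and 5 for female adult. Of the male one-sex clusters, only cluster 35 had large weights from both male libraries, with 46.8% from male pupa and 52.7% from male adult. Every other one had at least 84.4% of its weight from a single male library, so in males these clusters do not tell sex from library. A cluster mostly of 1 library may be that library rather than a cell type. Simulated groups of barcodes at these depths were split by depth, but 0 of the 10 resulting clusters were one-sex, and with real barcodes thinned to 500 molecules one-sex clusters held 80.3%.

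**Figure D4:**
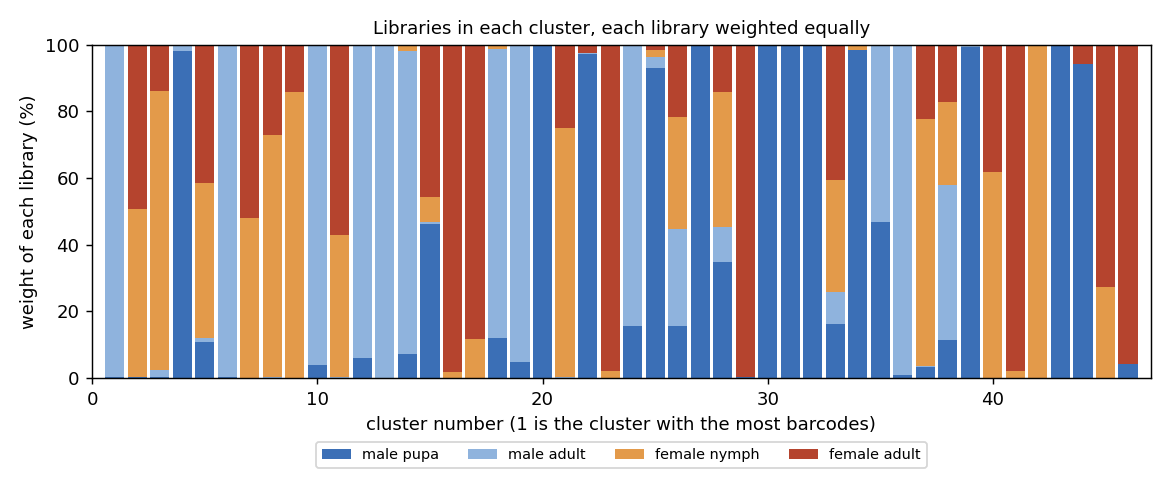
Weight of each library in percent (vertical axis) in each of 46 clusters (horizontal axis), after every library was given the same total weight. In 22 clusters at least 95% of the bar is male and in 17 at least 95% is female, and 4 clusters hold at least 5% of each library.

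Molecules of several named IDs lay mostly in 1 cluster of a library, and the clusters had been built from IDs that include such variable ones. All shares in this paragraph are of the molecules in clustered barcodes, those with at least 200 IDs, and not of the library totals given above. In male adult, these were 38202 of 42287 molecules of Ech006855, 24192 of 27240 of Ech004386 and 6270 of 6916 of Ech006248. Of the clustered molecules, cluster 36 (165 barcodes) held 96.5%, 97.3% and 96.5%. In male pupa, cluster 25 (325 barcodes) held 89.2% of Ech006855, 97.6% of Ech004386 and 64.4% of Ech006248 molecules. The female-higher IDs lay mostly in cluster 7, with 84.5% of Ech010436, 90.4% of Ech003845 and 91.8% of Ech010489 molecules of female nymph. In female adult the same cluster held 65.2% of 280546, 77.1% of 70003 and 62.8% of 36803 clustered molecules. In female nymph, cluster 42, with 107 barcodes of that library and none of another, held 95.6% of 498 clustered molecules of Ech010854 and 94.9% of 355 of Ech007459. Ech008062 lay in different clusters in the libraries that had it, with 90.9% of its male pupa molecules in cluster 22 and 67.4% of its female adult molecules in cluster 17. Ech010557 had 49.8% of its male pupa molecules in cluster 15 and 72.5% of its female adult molecules in cluster 29. Cluster 22 held 391 male pupa and 11 female adult barcodes, cluster 17 held 0 and 434, and cluster 29 held 1 and 280. Cluster 15, by contrast, held 246 and 251. Clusters 22, 17 and 29, so nearly without the other library, leave open whether the same kind of cell carried these IDs in both libraries. Cluster 15 does not settle this for Ech010557, because its makeup depended on the settings. Ech003336 was spread more widely in male adult, female nymph and female adult, where the cluster with most of it held 35.8%, 37.3% and 42.7% of its molecules. In male pupa the cluster with most of it held 67.2%. In female nymph it stood at 197.9 per 1000000 molecules in that cluster against 191.6 elsewhere. The other libraries had more of it inside, with 34.59 against 2.016 in male pupa, 5012 against 542.5 in male adult and 392.8 against 116.3 in female adult.

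At 500 molecules per barcode, Ech008062 was found in 14.8% of male pupa barcodes (13.8 to 15.9) and 8.33% of female adult barcodes (7.54 to 9.16), against 0.0778% in male adult and 0.0185% in female nymph. Without thinning the values were 28.2%, 16.1%, 0.0791% and 0.0336%. Inside and outside the cluster with most of its molecules, Ech008062 of male pupa was found without thinning in 98.7% of cluster 22 barcodes, at a median of 5585 molecules, and in 21.4% of the other clustered barcodes, at 3079. In female adult it was found in 57.6% of cluster 17 barcodes, at a median of 3805.5 molecules, and in 11.9% of the others, at 7251.5. Ech010557 was found at equal depth in 8.14% of male pupa (7.35 to 8.98) and 8.70% of female adult barcodes (7.90 to 9.55), and in 0 of 5142 in male adult and 0 of 5403 in female nymph. The upper limits of these zero shares were 0.0717% and 0.0683%. Without thinning, Ech010557 was found in 18.0% of male pupa, 16.3% of female adult, 0.0791% of male adult (7 of 8854) and 0 of 5949 female nymph barcodes. Without thinning it was found in 16.0% of male pupa barcodes outside cluster 15, at a median of 3193 molecules, against 53.3% inside at 3793.5. In female adult the share was 11.1% outside cluster 29, at 6902.5, against 98.2% inside at 5545. Ech010436 was found at equal depth in 25.5% of female nymph (24.4 to 26.7) and 29.4% of female adult barcodes (28.1 to 30.8), against 0.9496% in male pupa and 0.0194% in male adult. Without thinning it was found in 50.7% of female nymph, 75.2% of female adult, 3.22% of male pupa and 0.0452% of male adult barcodes. Outside cluster 7 it was found without thinning in 46.7% of female nymph barcodes at a median of 2655 molecules and in 72.7% of female adult barcodes at 7360. Shares inside and outside a cluster are of barcodes with at least 200 IDs. Shares outside a cluster can hold both free RNA and expression in other clusters, which were not separated, so the level of background in these shares is open.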

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

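The tests below of a mixed library and of counting noise were chosen after the result had been seen, and the bound for the mixed library was raised once its value was known. Stage ratios ran in opposite directions in the sexes for 207 IDs that were at least 4-fold lower in male adult than in male pupa and at least 4-fold higher in female adult than in female nymph. The opposite combination held 35 IDs. With 1 library per group, the difference between the sexes was not tested. Among the named IDs, Ech008062 had a log2 ratio of adult to pupa of -11.97 in males and of adult to nymph of 12.65 in females. The corresponding values of Ech010557 were -11.57 and 12.97.

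The 154 IDs higher in both male pupa and female adult all lie within these 207, which follows from how the pattern is defined. Molecules of the whole male pupa library in the female adult library would set a common floor for every abundant male pupa ID. To give the pattern, this floor would have to be near 0.566, the ratio of the pattern IDs together. Over 549 IDs chosen without the female adult library, 78 of them pattern IDs, the median ratio was 0.106. This median says nothing about Ech008062, whose own ratio lay below it. The 25th, 10th and 5th percentiles bound a floor more closely, at 0.0162, 0.00264 and 0.00131, and Ech008062 lay above them. Of the pattern's female adult molecules, 1.34% lay in barcode numbers that the male pupa library also had. Molecules of single cell types stay open. Counting noise of the shallow male adult library is argued against, because over 100 random splits of the molecules the IDs chosen in one part had, in the other part, a median log2 ratio of male adult to the lower of male pupa and female adult of -3.71 (-3.88 to -3.58), whereas a loss of whole kinds of cells from that library stays open. An exchange of stage labels within 1 sex stays open, since it needs opposite stage ratios within the same kinds of cells. With molecules summed over the 4 shared clusters, r across 5286 IDs was -0.112 (range of resampled counts -0.12 to -0.0979). This sum can also reflect how the barcodes of a library were divided among these clusters. In clusters 26, 28, 33 and 38 taken alone, r was -0.0909, -0.16, -0.224 and -0.206. Free RNA of each library could give the same sign. A difference between the sexes in the stage at which these transcripts are made stays open too and was not tested.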

How the results depend on the processing

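With 1 library per group, these settings show how values depend on choices and not how they would vary between animals. No paired analysis was possible because each group holds 1 library. The alternatives for gene lists were not run because the IDs have no names. A number of IDs or clusters was taken as kept when it stayed within 1.5 times. Percentages, medians and log2 ratios were taken as kept only when they stayed inside their 95% counting interval. For r, the range of resampled counts, -0.389 to -0.378, took the place of that interval. This range was not centred on r, so small moves of r past it carry little weight. By these rules 134 of the main results under an alternative kept their value and 33 moved. Of values of named IDs and single clusters, 259 kept and 105 moved. No numbers of IDs or clusters and no percentages could be recorded as reversed. That 0 results reversed therefore says nothing about them, and among the main results it speaks for r only. The causes of the moves were not tested, except where fewer libraries or another depth were the setting. The alternatives without male adult, without pattern IDs, without the highest doublet scores, with thinned clustering and without the IDs that differ 4-fold were chosen after seeing the data.

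The number of IDs higher in both adults went from 1 to 2 with median-of-ratios scaling. Without the male adult library, which removes a condition from each pattern, 120 IDs were higher in immature libraries, 44 in the adult library, 283 in male pupa and female adult, and 77 in female nymph. The correlation r of stage ratios stayed negative, at -0.392 with barcodes of at least 200 IDs, -0.393 with at least 500 molecules, -0.293 with the mean over barcodes, -0.37 with a minimum of 20 molecules and -0.24 without the pattern IDs. The percentage of barcodes in one-sex clusters was 81.0 at resolution 0.4, 86.9 at resolution 1.2, 84.3 with at least 100 IDs, 83.1 with at least 500 IDs, 93.8 with IDs centred within libraries, 84.5 without called doublets, 82.7 without the highest doublet scores, 80.3 with barcodes thinned to 500 molecules and 81.4 without the IDs that differ 4-fold. The percentage in shared clusters was 3.799 with centring, 5.53 without the highest doublet scores, 4.03 with thinned barcodes and 7.78 without the IDs that differ 4-fold. Female one-sex clusters numbered 11 at resolution 0.4 and 10 with thinned barcodes. Median IDs per barcode were 626 in male pupa, 583 in male adult, 547 in female nymph and 532 in female adult at 1000 molecules, and 1407, 351, 1046 and 1840 without thinning.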

Other observations

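The tests of 1 common depth factor and of ID order below were chosen after the results had been seen, as was that of free RNA inside shared clusters, which took the place of a first test against the profile of the whole library. The depth factor was set against each other library after its value against their mean was known, and the account of free RNA in male adult was narrowed to a single well-mixed source after its value was known. The 154 IDs higher in male pupa and female adult took over 5% of molecules in a minority of barcodes only. These were 844 of 4427 male pupa barcodes (19.1%, 17.9 to 20.2) and 671 of 4578 female adult barcodes (14.7%, 13.6 to 15.7), against 4 in male adult and 6 in female nymph. The median share per barcode was 0.688% in male pupa, 0.448% in female adult, 0% in male adult and 0.0433% in female nymph. The low numbers in male adult and female nymph follow from how the IDs were chosen and are no added evidence. Of their molecules in barcodes with at least 200 IDs, 54.0% lay in cluster 22 in male pupa, and in female adult 44.8% lay in cluster 29 and 21.9% in cluster 17. Cluster 15 held barcodes of both libraries, 246 of male pupa and 251 of female adult, with 5 of male adult and 52 of female nymph. It held 13.5% of those molecules in male pupa and 9.66% in female adult. Its makeup depended on the settings. It held 5.56% of male pupa barcodes, and the cluster that matched it best held 14.3% at resolution 0.4, 12.3% with at least 100 IDs per barcode, 1.45% with at least 500 and 0.226% with IDs centred and scaled within libraries. Of female adult barcodes the same clusters held 5.72%, 5.62%, 5.25% and 6.14%, against 5.48%.

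Male adult had few molecules per barcode, with 2 clusters, 1 and 13, at medians of 484 and 449. Free RNA of a single well-mixed source is argued against as all that the shallow barcodes hold, because 79.1% of 4421 male adult barcodes below the library median lay beyond the 99th percentile of draws from their pooled profile, but free RNA that varies between barcodes was not measured and stays open. A single depth factor for all barcodes stays open, because the other libraries differ among themselves: the median and the 95th percentile were 4.77-fold and 4.64-fold below those of female nymph (quotient 0.971), but 5.41-fold and 3.15-fold below male pupa (0.584) and 11.2-fold and 4.23-fold below female adult (0.379). A mix of depth, smaller cells and the pipeline's choice of barcodes may remain, and the earlier pipeline run of this library cannot be separated from its group.

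Inside the 4 shared clusters, sex-higher IDs were still present, at levels that differed between the clusters. The 237 female-higher IDs took 6.03% of molecules in female nymph and 4.42% in female adult, against 0.637% in male pupa and 0.734% in male adult, summed over these clusters. Clusters 26 and 28 carried most of these female-higher molecules, with 5.96% and 10.01% in female nymph against 0.747% and 1.60% in clusters 33 and 38. Cluster 28 depended on the settings, and the cluster that matched it best held 0.304% of male pupa barcodes with at least 500 IDs and 3.07% with thinned barcodes, against 2.01%. The 758 male-higher IDs were divided otherwise. In male pupa and male adult they took 0.9325% and 1.135% in cluster 26, 5.93% and 9.38% in cluster 28, 1.18% and 1.56% in cluster 33, and 3.17% and 3.999% in cluster 38. A single source of free RNA would keep the relative amounts of its IDs in every cluster of a library, but r of log molecules between clusters 26 and 33, across the IDs higher in the library's own sex with at least 20 molecules in these clusters, was -0.685 in male pupa, -0.325 in male adult, 0.281 in female nymph and 0.32 in female adult, where random splits at 1 ratio gave 2.5th percentiles of 0.904, 0.827, 0.921 and 0.939. This argues against a single source of free RNA as the whole source of these molecules in clusters 26 and 33 together. The clusters were built from variable IDs that can include these IDs, and a few cluster-specific IDs can lower r. How much of these molecules was free RNA was therefore not measured. Clusters 28 and 38 were not compared, and a part from such a source stays open in all of them.

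Ratios of IDs with neighbouring numbers were weakly correlated. For pairs of IDs with consecutive numbers, r of log2 ratios was 0.0913 for male adult against male pupa, 0.134 for female adult against female nymph, 0.163 for female adult against male adult and 0.181 for female nymph against male pupa. The highest r of 1000 random orders was 0.0411, 0.051, 0.0362 and 0.0476 in the same order of comparisons.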
